A study of Homo sapiens with 12 samples.

How the data were processed

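Messenger RNA was sequenced from 2 human small cell lung cancer lines, H82 and H211, grown with the LSD1 inhibitor ORY-1001 at 1 µM or with vehicle. Each of the 4 groups held 3 libraries, 12 in all, and groups and replicate numbers were taken from the sample descriptions. The sample labels give the treatment as 7 days and the treatment protocol gives 10 days; which of these applied was not settled here. The labels do not say that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

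Per the labels' protocols, mRNA was enriched with oligo(dT) beads, libraries were made with the NEBNext Ultra II kit, and paired-end reads from an Illumina HiSeq were demultiplexed with bcl2fastq 2.17. Per the submitters' processing notes, Trimmomatic 0.36, STAR 2.5.2b, featureCounts from Subread 1.5.2, DESeq2, Salmon 1.1.0, sleuth 0.30.0 and R 4.0.4 were used with the hg38 build; the role and order of each tool is not given in the sources used here. The annotation release behind the gene symbols is not given in the sources used here.

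The deposited table holds a TPM-like signal for 56508 gene symbols in 12 columns, and no column was without a sample. The deposited signal is TPM that appears to have been rescaled between libraries: column totals ran from 967415 to 1111988, where plain TPM would give the same total in each. Median-of-ratios factors of the columns lay between 0.9928 and 1.031. The tests had been planned for TPM, and the same log-scale tests were used for this rescaled TPM. Read counts were not analysed here, so the depth of each library is unknown and no counting error can be given; rescaled TPM keeps no depth. Of the symbols, 24415 were at 0 in every library. Another 27 rows carried dates in place of gene symbols, 21 of which were tested; these were not named.

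Values were analysed as log2(TPM + 1), so that a log2 fold change understates the change of genes with low values. Genes with a value of at least 1 in at least 3 libraries were kept, which left 15456. One linear model with 4 group means was fitted to all 12 libraries with limma 3.58.1 in R 4.3.3 (eBayes with a trend), and p-values were two-sided with Benjamini-Hochberg adjustment over genes, called at an adjusted p under 0.05. Contrasts were ORY-1001 against control in H82 and in H211, the difference between these effects (H211 minus H82), their average, and the H211 against the H82 controls. Folds given beside means are ratios of group means, and errors are SD over 3 libraries or the standard error (SE) of the log2 fold change. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a contrast; 26 lists were fixed before the data were examined, and 25 had at least 5 measured members. The endothelial marker list had 0 measured genes and was not tested. Camera with an estimated correlation and fry were alternatives, and 3 further lists (hypoxia, immediate early and ribosomal protein genes) were chosen after the data were examined.

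The genes named were set by a rule fixed before the data were examined. It took, in each line, the 6 called genes with the largest rise and the 6 with the largest fall that had a mean of at least 5 in the higher group and no overlap between the 3 treated and 3 control libraries. It added the 4 largest differences each way between the lines, with a mean of at least 5 in at least 1 group, and a set of genes of interest in every contrast. From each list with a called member it took up to 2 members by smallest p; they are named for lists that passed their test, and the other lists are given by counts. In the control cultures it took the subtype transcription factors and up to 2 members of each list. Clone names, pseudogenes, XIST and Y-linked genes were left out, and some genes the rule takes are not reported here. For the 3 lists chosen later, the 2 members with the smallest p were named after their values were seen. Positions come from GENCODE release 29 on GRCh38, which matched 55883 of the 56508 symbols by name and 15305 of the tested ones; it need not be the annotation the authors used. Genes of the HLA family share sequence with each other, and how their reads were divided is not known, so their separate levels are uncertain.

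The fit was tested on simulated data with 200 genes changed in 1 line, 100 at each of 2 fold sizes, over 10 simulations per line. In H82, 62.8% of genes changed 1.5-fold and 92.1% of genes changed 3-fold were recovered, among a median of 15066.5 genes tested, and 6.01% of calls were false. In H211, 61.5% and 92.2% were recovered among a median of 15072.5 genes, and 4.95% of calls were false. A first run with a single simulation had given a false share above the limit of 10% set for it, and 10 simulations were then pooled with the same seed. Alternatives planned before the data were examined changed the pseudocount, the filter, the scaling, the variance prior, the library weights, the samples in the fit, the replicate block and the list test, and left out each library in turn. After the data were examined, 3 more were added: without 4 libraries that stood apart in blood-cell transcripts (H82 ORY-1001 replicate 3, H211 control replicates 1 and 2, and H211 ORY-1001 replicate 3; H82 ORY-1001 replicates 1 and 2, which also carried such transcripts, were kept), without genes under 3% of their level in the other line, and with at least a 2-fold change. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.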

Results

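Messenger RNA was measured in H82 and H211, 2 established human small cell lung cancer lines, to compare cultures with and without inhibition of LSD1. LSD1, encoded by KDM1A, is a histone demethylase, and ORY-1001 is its inhibitor. Each line was sampled with ORY-1001 at 1 µM and with vehicle, in 3 libraries each. All levels are in the deposited rescaled TPM, given as mean ± SD over 3 libraries. The depth behind each value is unknown, so no counting interval can be given. Libraries of a group correlated at r = 0.9881 to 0.9912 across genes, treated and control libraries of a line at 0.9715 to 0.9819, and libraries of different lines at 0.7861 to 0.8069; genes are not independent replicates. The first principal component held 86.5% of the variance and parted the lines. KDM1A itself lay at 184 ± 2.43 in H82 controls and 190 ± 8.17 with ORY-1001, and at 185 ± 2.57 and 188 ± 4.68 in H211, with adjusted p = 0.354 and 0.663.

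Transcripts of blood cells differed between libraries of a group. Fetal globin HBG2 was at 53.02 in H82 ORY-1001 replicate 3 and at 0 and 0.1204 in replicates 1 and 2. The H82 controls held it at 23.9, 28.15 and 22.43, and H211 ORY-1001 replicates 1, 2 and 3 at 22.35, 16.84 and 0. In H211 controls it was at 47.39, 40.62 and 18.67. MPO, the myeloperoxidase of neutrophils, was at 24.26 in H82 ORY-1001 replicate 3 and 24.27 in H211 control replicate 1. It stood at 8.707, 8.547 and 8.571 in H82 ORY-1001 replicates 1 and 2 and H211 ORY-1001 replicate 3, and under 1 in the other libraries. LYZ, lysozyme, was at 22.99 in H211 control replicate 2 and at 0.3561 and 0.2259 in the other controls of H211. It was also at 15.98 and 18.69 in H82 ORY-1001 replicates 1 and 2 and 16.05 in H211 ORY-1001 replicate 3. The first 2 of these are kept in the fit without 4 libraries that is given below, so that fit still holds blood transcripts.

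**Figure D1:**
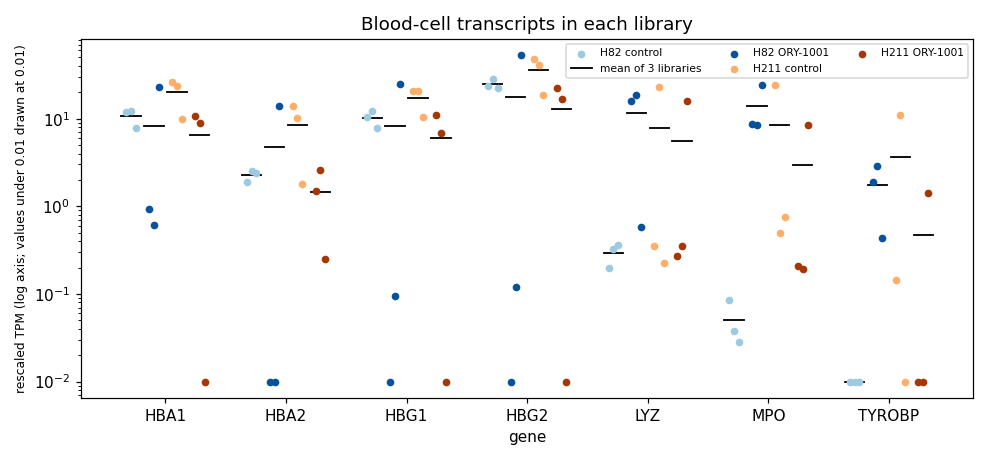
Blood-cell transcripts in each library, in rescaled TPM on a log axis with values under 0.01 drawn at 0.01. Points are libraries and bars are means of 3 libraries; HBG2 ran from 0 to 53.02 within the H82 ORY-1001 group.

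The control cultures showed how the lines differ without the drug. H82 controls carried NEUROD1, a neuronal bHLH factor on chromosome 2 (181673088 to 181680876), at 137 ± 2.16 against 1.69 ± 0.366 in H211, 81.5-fold higher. H211 controls carried POU2F3, the master factor of tuft cells on chromosome 11 (120236640 to 120319944), at 281 ± 3.91 against 2.31 ± 0.478 in H82, 122-fold higher. ASCL2, a bHLH factor, and BMX, a tyrosine kinase, both on the tuft-cell list, were 207-fold and 140-fold higher in H211. MYC was 4.49-fold higher in H82, at 1915 ± 30.3 against 426 ± 16.2, and MYCL was 15-fold higher in H82. SOX11, NFIB and INSM1 were higher in H82 by 89.2-fold, 3.27-fold and 3.23-fold, and SOX4, PROX1, MYCN, REST, YAP1 and GFI1B were higher in H211 by 6.43-fold, 10.2-fold, 5.41-fold, 2.15-fold, 14.6-fold and 32.5-fold. Adjusted p for these genes ran from 3.29e-14 to 0.00117. YAP1 averaged under 1 in the controls of both lines, so its fold rests on low values. Among the other genes of interest, NOTCH2 was 2.87-fold higher in H82, and B2M 2.27-fold and TAP1 11.8-fold higher in H211. KDM1A and HES1 had adjusted p = 0.954 and 0.115. HLA-B, with H211 control values of 1.686, 16.1 and 0.4055, had adjusted p = 0.111, and 0.00808 without H211 control replicate 3; HES1 reached 0.0491 without H82 control replicate 1. The HLA-B value of 16.1 was in H211 control replicate 2, where LYZ was at 22.99.

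Of 25 lists tested, 12 differed between the control cultures, and none of the 12 calls held with an estimated correlation (adjusted p = 0.169 to 0.264). Tuft-cell genes were higher in H211 in 15 of 18 measured (3 lower; median log2 difference 4.67, adjusted p = 4.81e-05), as were epithelial-mesenchymal genes in 16 of 22 (6 lower; 0.0188), with EPCAM 130-fold and KRT19 29.6-fold higher. Non-neuroendocrine markers were higher in 14 of 19 and lower in 5 (adjusted p = 0.0471); ANXA1 was 91.4-fold higher in H211 and S100A16 7.15-fold higher in H82. Interferon-stimulated genes were higher in H211 in 17 of 25 and lower in 6 (0.0327), and nucleic acid sensing genes in 8 of 11 and lower in 1 (0.0346). ISG15 and USP18 were 45.5-fold and 12.2-fold higher, and the sensors IFIH1 and CGAS 121-fold and 98.2-fold. Cholesterol synthesis genes were higher in H211 in 14 of 18 and lower in 2 (0.0142), with SQLE 4.26-fold and FDFT1 3.53-fold, and replication histone genes in 9 of 11 with 0 lower (0.0279), with HIST3H2A 10.4-fold and HIST1H1C 2.07-fold.

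Neuroendocrine markers were higher in H82 in 21 of 25 and lower in 2 (median log2 difference H211 minus H82 -1.59, adjusted p = 0.000278). RTN1, a reticulon of neurons, was 67-fold and DLL3, an inhibitory Notch ligand, 6.11-fold higher in H82. The neuronal bHLH program was higher in H82 in 11 of 15 and lower in 3 (0.0188), with OTX2 72.6-fold. Ion channels and synapse genes were higher in H82 in 14 of 19 and lower in 3 (0.0346), with KCNH2 the other way, 9.7-fold higher in H211. Cell cycle genes were higher in H82 in 17 of 26 and lower in 5 (0.0378), with AURKB 4.81-fold and CDC20 3.49-fold, and integrated stress response genes in 12 of 19 and lower in 2 (0.0346), with PSAT1 4.23-fold higher in H82 and ATF5 5.65-fold higher in H211. Adjusted over the list alone, the counts of these 12 lists were the same. The call of non-neuroendocrine markers was lost without H211 control replicate 1 or 2 or H211 ORY-1001 replicate 3 (adjusted p = 0.0539, 0.0616 and 0.0536). Non-neuroendocrine markers also lost it with a pseudocount of 0.1 (0.0709), among genes at 5 or more in 3 libraries (0.115) and with median-of-ratios or quantile scaling (0.0533 and 0.0586). Ion channel genes lost theirs among genes at 5 or more in 3 libraries (0.233). Totals without the mitochondrial genes, and the fit without the 4 libraries that stood apart in blood transcripts, ended the calls of 5 lists. These were non-neuroendocrine, interferon-stimulated, nucleic acid sensing, cell cycle and stress response genes (0.0506 to 0.116, and 0.0564 to 0.0989). The other 13 lists had adjusted p = 0.127 to 0.968.

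Over all genes, 12442 of 15456 differed between the control cultures, 6139 higher in H211 and 6303 higher in H82; 5852 differed at least 2-fold. With totals without the mitochondrial genes, 6941 were higher in H211 and 5474 in H82. One line stands for each background, so this compares these lines only. Of 1366 genes at 100 or more in H82, the lowest stood at 1.23% of that level in H211, and of 1405 such genes of H211 the lowest above 0 stood at 0.406% in H82, so low values of genes abundant in the other line, among them those of NEUROD1 and POU2F3, lie near these traces.

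In H82, genes of MHC class I antigen presentation were higher with ORY-1001, several from levels under 1. TAP1, a subunit of the peptide transporter, on chromosome 6 (32845209 to 32853978), rose from 0.296 ± 0.0965 to 21.8 ± 0.328, 73.6-fold (log2 fold change 4.14, SE 0.079, adjusted p = 1.65e-10). TAP2, its partner, rose 49.4-fold, from 0.324 ± 0.328 to 16 ± 1.16, and PSMB8, an immunoproteasome subunit, 43.2-fold, from 0.393 ± 0.207 to 17 ± 0.945. The heavy chains HLA-B and HLA-C rose 23.4-fold and 10.9-fold, from 0.753 ± 0.275 and 5.03 ± 0.435. B2M, the light chain, rose 5-fold, from 90.8 ± 6.05 to 454 ± 39.3. Of 21 measured genes of the list, 15 rose and 1 fell, and 16 and 1 adjusted over the list alone (median log2 fold change 0.759, adjusted p = 1.38e-08, and 0.0355 with an estimated correlation). HLA genes share sequence, and TAP1, PSMB8 and PSMB9 overlap on the annotation, so how reads were divided among them is not known. Blood markers also lay above every control in the treated libraries of H82. LYZ was at 15.98, 18.69 and 0.5834, MPO at 8.707, 8.547 and 24.26 and TYROBP at 1.9, 2.914 and 0.4391, where TAP1 was at 21.86, 21.44 and 22.08.

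**Figure D2:**
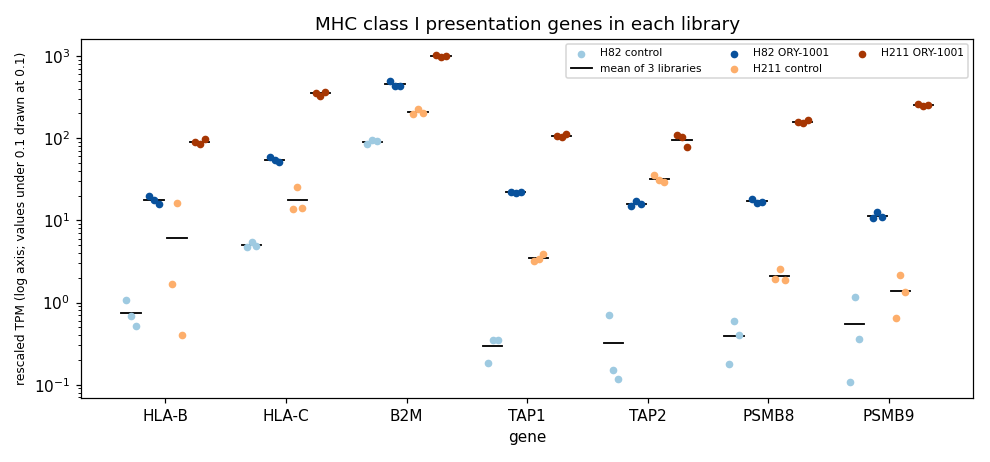
MHC class I presentation genes in each library, in rescaled TPM on a log axis with values under 0.1 drawn at 0.1. Points are libraries and bars are means of 3; TAP1 averaged 0.296 in H82 controls and 21.8 with ORY-1001, and 3.49 and 107 in H211.

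Neuroendocrine, synaptic and stress response genes fell in H82. NSG1, a protein of neuronal endosomes, on chromosome 4 (4348140 to 4419058), fell from 148 ± 2.71 to 8.09 ± 0.914, 18.2-fold lower (log2 fold change -4.04, SE 0.135, adjusted p = 4.33e-09). PRSS56, a serine protease, was 46.2-fold lower, from 12.5 ± 0.257 to 0.271 ± 0.0232. CPLX3, a complexin of synaptic vesicle release, was 7.87-fold lower, and PCOLCE, an enhancer of procollagen processing, 10.4-fold lower. ASNS, asparagine synthetase, fell from 649 ± 27.1 to 90.6 ± 5.3, 7.16-fold lower (adjusted p = 3.19e-10). Neuroendocrine markers fell in 21 of 25 and rose in 2, with the same counts adjusted over the list alone (median -0.892, adjusted p = 2.5e-07). That call was lost with an estimated correlation (adjusted p = 0.143). SYT1, the calcium sensor of vesicle fusion, was 1.91-fold lower and the adhesion molecule NCAM1 1.83-fold lower. INSM1, a neuroendocrine zinc finger factor, was 1.48-fold lower (adjusted p = 0.00859). Ion channels and synapse genes fell in 10 of 19 and rose in 1, and 11 and 1 adjusted over the list alone (median -0.587, adjusted p = 0.00238). With an estimated correlation their adjusted p = 0.143, and 0.0509 among genes at 5 or more in 3 libraries. The synapsin SYN1 was 3.29-fold lower.

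Integrated stress response genes fell in 16 of 19 and rose in 2, with the same counts adjusted over the list alone (median -0.84, adjusted p = 1.6e-07, and 0.00718 with an estimated correlation). ASNS led the falls. DDIT4, an inhibitor of mTORC1, went the other way, from 29.3 ± 2.67 to 210 ± 8.7, 7.16-fold higher (adjusted p = 8.94e-10). Cholesterol synthesis genes rose in 15 of 18 and fell in 1, and 16 and 1 adjusted over the list alone (median 0.427, adjusted p = 1.42e-07, and 0.01 with an estimated correlation). HMGCS1, the HMG-CoA synthase, rose 2.72-fold, from 24.4 ± 1.81 to 66.4 ± 2.49, and FDFT1, the squalene synthase, 1.63-fold. Interferon-stimulated genes rose in 8 of 25 and fell in 2, with the same counts adjusted over the list alone (median 0.184, adjusted p = 0.0319). USP18, which removes ISG15 from proteins, rose 6.47-fold and IFI6 3.52-fold. The call of this list was lost with an estimated correlation (adjusted p = 0.432), with a pseudocount of 5 (0.0509) and with the replicate number as a block (0.0503). It was also lost without H82 ORY-1001 replicate 3 (median 0.099, adjusted p = 0.084) and without the 4 libraries that stood apart in blood transcripts (0.0671).

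Over all genes, 6643 changed in H82, 2949 higher and 3694 lower with ORY-1001; 206 rose and 323 fell at least 2-fold. With quantile normalization 3296 were higher and 3304 lower. In blood transcripts every treated library of H82 differed from all 3 controls. HBG2 was at 23.9, 28.15 and 22.43 in controls and at 0, 0.1204 and 53.02 with ORY-1001. The effect of ORY-1001 in H82 therefore cannot be told apart from that of whatever set these libraries apart. Each gene named for the size of its rise or fall lay beyond all 3 controls in all 3 treated libraries. The naming rule required this, so it is no evidence for an effect of the drug. MPO was among the largest rises, at 0.0503 ± 0.0303 in controls and 13.8 ± 9.03 with ORY-1001 (adjusted p = 0.0141), in libraries that also differed in the blood transcripts above; without H82 ORY-1001 replicate 3 its adjusted p = 0.052. SNORD15B, a small nucleolar RNA, was at 8.048, 5.973 and 8.1 in controls and listed at 0 in the treated libraries (adjusted p = 0.0203, and 0.0527 or 0.0532 without H82 control replicate 1 or 3). NEUROD1, YAP1, REST, NOTCH2, HES1 and GFI1B had adjusted p = 0.499, 0.771, 0.898, 0.742, 0.0879 and 0.763; HES1 reached 0.0469 without H82 control replicate 1 and GFI1B 0.0409 without H82 ORY-1001 replicate 3. POU2F3 had a log2 fold change of -0.312 (adjusted p = 0.0433), which passed the threshold when H82 control replicate 2 or H82 ORY-1001 replicate 1 was left out, and missed it when any other library was (0.0541 to 0.164).

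In H211, genes of MHC class I presentation were higher with ORY-1001. PSMB9, an immunoproteasome subunit, on chromosome 6 (32844136 to 32859585), rose from 1.37 ± 0.75 to 253 ± 6.93, 184-fold (log2 fold change 6.79, SE 0.246, adjusted p = 1.08e-08). PSMB8 rose 74.6-fold, from 2.12 ± 0.37 to 158 ± 7.64, and TAP1 30.7-fold, from 3.49 ± 0.364 to 107 ± 5.75 (adjusted p = 2.6e-11). HLA-C rose 19.5-fold, from 17.8 ± 6.81 to 349 ± 17.7 (adjusted p = 4.51e-08). HLA-B rose 14.9-fold to 90.5 ± 7.01, from controls at 1.686, 16.1 and 0.4055 (log2 fold change 4.508, adjusted p = 0.00078; 5.554 without control replicate 2 and 3.751 without control replicate 3), and B2M 4.83-fold, from 206 ± 15.7 to 995 ± 22.3. The HLA-B value of 16.1 was in control replicate 2, which also held LYZ at 22.99 and TYROBP at 10.92. Its source was not tested. Of the 21 genes 17 rose and 0 fell, and 17 and 1 adjusted over the list alone (median 1.56, adjusted p = 5.6e-21, and 0.00326 with an estimated correlation).

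Interferon-stimulated genes rose with them in H211, 17 of 25 with 0 lower, and 18 and 0 adjusted over the list alone (median 0.679, adjusted p = 3.34e-15, and 0.00584 with an estimated correlation). IFITM3, a membrane restriction factor, rose 9.3-fold, from 9.3 ± 0.728 to 86.5 ± 0.358. EGR1, an immediate early transcription factor on chromosome 5 (138465490 to 138469315), rose 27.7-fold, from 12.1 ± 1.04 to 336 ± 29.3 (log2 fold change 4.68, SE 0.247, adjusted p = 2.62e-07). TGF-beta pathway genes rose in 7 of 20 and fell in 1, with the same counts adjusted over the list alone (median 0.151, adjusted p = 0.00353, and 0.0329 with an estimated correlation). Its targets ID3 and ID1 rose 2.16-fold and 1.74-fold. YAP1, the Hippo pathway coactivator, rose 6.22-fold from a low level, 0.914 ± 0.164 to 5.69 ± 0.482 (adjusted p = 3.62e-07). GFI1B, a repressor that recruits LSD1, rose 1.84-fold, from 13.5 ± 0.927 to 24.8 ± 1.05 (adjusted p = 0.00252, and 0.161 with a pseudocount of 0.1). HES1, a Notch target, was at 0.567 ± 0.0999 in controls and 1.39 ± 0.22 with ORY-1001 (adjusted p = 0.00513).

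Tuft-cell genes fell in 10 of 18 and rose in 1 in H211, and 11 and 1 adjusted over the list alone (median -0.474, adjusted p = 1.41e-06). With an estimated correlation the call was lost (adjusted p = 0.189). PTGS1, the constitutive cyclooxygenase, on chromosome 9 (122370530 to 122395703), fell from 11.6 ± 1.03 to 0.922 ± 0.0419, 12.6-fold lower (log2 fold change -2.71, SE 0.095, adjusted p = 8.52e-09), and CHAT, choline acetyltransferase, was 4.18-fold lower. Other large falls were those of S100A14, a calcium-binding protein (7.46-fold), PRKAR2B, a protein kinase A subunit (5.26-fold), ANXA1, an annexin (5.2-fold, from 359 ± 20.2 to 69 ± 1.23), SPIB, an ETS factor (5.1-fold), and ALDH1A1, a retinaldehyde dehydrogenase (3.9-fold). POU2F3 was at 281 ± 3.91 in controls and 251 ± 9.85 with ORY-1001 (adjusted p = 0.37, and 0.034 with each line fitted alone).

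Cholesterol synthesis genes fell in H211, 15 of 18 with 0 higher, and 17 and 0 adjusted over the list alone (median -0.361, adjusted p = 8.48e-13, and 0.00326 with an estimated correlation). INSIG1, which restrains SREBP, was 1.72-fold lower. Integrated stress response genes fell in 10 of 19 and rose in 2, and 12 and 2 adjusted over the list alone (median -0.251, adjusted p = 0.000995, and 0.0233 with an estimated correlation). ATF3, a stress-induced factor, rose 3.12-fold, and DDIT4 was 1.61-fold lower. Cell cycle genes fell in 9 of 26 with 0 higher, and 11 and 1 adjusted over the list alone (median -0.053, adjusted p = 0.0209, 0.301 with an estimated correlation, and 0.0764 without H211 control replicate 3). TOP2A and MCM3, which act in replication, were 1.21-fold and 1.17-fold lower. Replication histone genes rose in 2 of 11 and fell in 0, and 4 and 0 adjusted over the list alone (median 0.319, adjusted p = 0.013, and 0.074 with an estimated correlation). Chemokines and cytokines rose in 1 of 6, NFKBIA at 1.25-fold, and fell in 0, and 2 and 0 adjusted over the list alone (median 0.353, adjusted p = 0.0493). That call was lost with an estimated correlation (0.301), with other settings, among them median-of-ratios scaling (0.0508) and a pseudocount of 5 (0.0809), and without H82 control replicate 2 (0.0527), any 1 control of H211 (0.059, 0.0546 and 0.083) or H211 ORY-1001 replicate 3 (0.142).

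Over all genes, 2868 changed in H211, 1383 higher and 1485 lower with ORY-1001; 140 rose and 91 fell at least 2-fold. The split moved to 958 higher and 1984 lower when totals left out the mitochondrial genes. The 2 arms of H211 also differed in blood transcripts. HBG2 was at 47.39, 40.62 and 18.67 in controls and at 22.35, 16.84 and 0 with ORY-1001. Only control replicate 3 and ORY-1001 replicates 1 and 2 were alike in it. The effect of ORY-1001 in H211 therefore cannot be fully told apart from that of whatever set these libraries apart. Without the 4 libraries that stood apart in blood transcripts, which leave 1 control of H211, 665 genes were called, 572 of them among the 2868; MCM3, NFKBIA and HES1 (adjusted p = 0.0806, 0.219 and 0.0595) and the replication histone list (0.112) then lost their calls. NEUROD1, REST, NOTCH2 and INSM1 had adjusted p = 0.391, 0.309, 0.0662 and 0.501; NEUROD1 reached 0.0474 without H211 control replicate 2, and NOTCH2 0.0498 without H211 control replicate 1 and 0.0386 with quantile normalization.

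**Figure D3:**
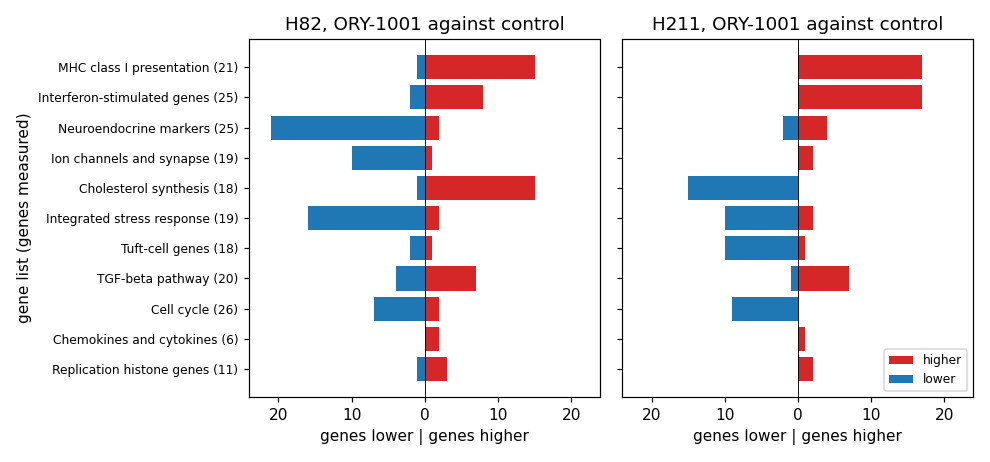
Number of genes called higher (right) and lower (left) with ORY-1001 in each line, for the fixed lists that passed their test in at least 1 line; the number measured stands beside each name. Cholesterol synthesis had 15 genes higher in H82 and 15 lower in H211.

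Lists that passed in neither line showed calls both ways or few calls. Members higher and lower in H82, then in H211, numbered 8 and 5, then 4 and 1 for the Notch pathway (21 measured), 3 and 5, then 10 and 5 for epithelial-mesenchymal genes (22), and 2 and 9, then 3 and 3 for the LSD1-CoREST complex (21). They numbered 3 and 6, then 2 and 1 for the neuronal bHLH program (15), 1 and 5, then 2 and 2 for subtype transcription factors (12), and 2 and 4, then 4 and 5 for non-neuroendocrine markers (19). Growth arrest and apoptosis genes counted 5 and 5, then 3 and 5 (19), immune ligands and checkpoints 3 and 5, then 1 and 3 (12), and nucleic acid sensing genes 4 and 3, then 3 and 1 (11). MHC class II genes counted 0 and 2, then 0 and 0 (6), fibroblast markers 0 and 2, then 1 and 0 (7), and mitochondrially encoded genes 0 and 1, then 0 and 0 (13). Myeloid markers counted 1 and 0, then 0 and 0 (7), and lymphoid and blood markers 0 and 0, then 0 and 1 (5); both hold the blood transcripts that differed between libraries of a group. Adjusted p for these lists ran from 0.335 to 0.922 in H82 and from 0.0555 to 0.956 in H211. Adjusted over the list alone, these counts were the same except for mitochondrially encoded genes in H82 (0 and 0) and, in H211, Notch (5 and 2), epithelial-mesenchymal (10 and 7), non-neuroendocrine (5 and 7), growth arrest (4 and 5), immune ligand (2 and 3) and nucleic acid sensing genes (3 and 3). Of the lists called in H211 alone, TGF-beta genes counted 7 and 4 in H82 (adjusted p = 0.0696), tuft-cell genes 1 and 2 (0.476), cell cycle genes 2 and 7 (0.335), chemokines 2 and 0 (0.128) and histone genes 3 and 1 (0.43). Adjusted over the list alone, these were 8 and 4, 0 and 0, 1 and 7, 4 and 0, and 3 and 1. Of those called in H82 alone, neuroendocrine markers counted 4 and 2 in H211 (0.0504) and ion channel genes 2 and 0 (0.339), or 5 and 3, and 0 and 0, adjusted over the list alone. Leaving out 1 library brought some under the threshold. Without H82 ORY-1001 replicate 1, TGF-beta genes had 0.0324 in H82. In H211, neuroendocrine markers had 0.000866 without control replicate 3 and 0.0452 or 0.0197 without ORY-1001 replicate 1 or 3, and epithelial-mesenchymal genes 0.0404 without control replicate 2 and 0.0461 without ORY-1001 replicate 1. Lymphoid and blood markers in H211 had 0.0148 without H82 ORY-1001 replicate 3 and 0.0356 or 0.042 without H211 ORY-1001 replicate 1 or 2, and mitochondrially encoded genes 0.0353 without the latter. Other settings did so as well. In H211, neuroendocrine markers had 0.0429 with the replicate number as a block and 0.0117 to 0.021 with a pseudocount of 0.1, no filter, totals without the mitochondrial genes or library weights; without the 4 libraries their median turned to -0.042 (0.956). Lymphoid and blood markers had 0.034 with the block, 0.0415 with each line fitted alone and 0.001 with no filter. Epithelial-mesenchymal genes had 0.0213 to 0.0304 with a pseudocount of 0.1, no filter or totals without the mitochondrial genes, and a median of -0.082 (0.515) among genes at 5 or more in 3 libraries. TGF-beta genes in H82 had 0.0267 with no filter and 0.0483 with quantile normalization, and cell cycle genes in H82 had 0.0309 and 0.0452. Further lists that gained a call with fry or without the 4 libraries are given below. Median, mean and test differed in sign for MHC class II, non-neuroendocrine, growth arrest and fibroblast genes in H82, and for growth arrest, LSD1-CoREST and Notch genes in H211.

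The responses of the lines were then set against each other. Differences are given as the H211 effect minus the H82 effect on the log2 scale. The H82 and H211 effects enter these differences, and the shared directions and the average below. With them enter the splits of the libraries of both lines in blood transcripts. EGR1 differed by 4.95 (SE 0.349, adjusted p = 2.86e-06), NSG1 by 4.13 (SE 0.191, adjusted p = 1.14e-07) and PSMB9 by 3.74 (SE 0.348, adjusted p = 2.17e-05). In the other direction, DDIT4 differed by -3.45 (SE 0.106, adjusted p = 6.57e-09) and MIR210HG, the host transcript of the hypoxia-linked miR-210, by -3.55 (SE 0.242, adjusted p = 2.27e-06). YAP1 differed by 1.76, with the rise in H211. B2M did not pass the test of the difference (-0.04, SE 0.1, adjusted p = 0.799). TAP1 differed by 0.454 (adjusted p = 0.0094), which turned to -0.915 (0.011) with a pseudocount of 0.1 and reached 0.208 without the 4 libraries. HLA-B differed by 1.09 (adjusted p = 0.409), and by 2.14 (0.000743) without H211 control replicate 2. INSM1 and GFI1B differed by 0.692 and 0.901 (adjusted p = 0.0197 and 0.00674), the latter with 0.119 at a pseudocount of 0.1. KDM1A, NEUROD1, POU2F3, REST, NOTCH2 and HES1 had adjusted p = 0.828, 0.243, 0.513, 0.362, 0.222 and 0.161, with 0.0248 for NEUROD1 without H211 control replicate 2 and 0.0476 for NOTCH2 without the 4 libraries.

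Gene groups differed between the lines as well. Cholesterol synthesis genes differed in 17 of 18, all toward H82, with 0 the other way (median -0.788, adjusted p = 3.68e-13, and 0.00271 with an estimated correlation). Integrated stress response genes differed in 14 of 19 toward H211 and 2 toward H82 (median 1.01, adjusted p = 1.7e-06, and 0.00605 with an estimated correlation); 9 fell in both lines. The next 5 lists were called at the preset correlation and lost the call with an estimated one (adjusted p = 0.431 for tuft-cell genes and 0.163 for each of the others). Neuroendocrine markers differed in 19 of 25 toward H211 and 1 toward H82 (median 0.989, adjusted p = 4.51e-08), and ion channels and synapse genes in 11 of 19 and 1 (0.924, 0.00136). MHC class I genes differed in 11 of 21 toward H211 and 2 toward H82 (median 0.558, adjusted p = 0.00053), with 14 raised in both lines, and interferon-stimulated genes in 13 of 25 and 2 (0.611, 0.00053), with 8 raised in both. With a pseudocount of 0.1 these 2 lists lost the call as well (0.114 and 0.0802). Tuft-cell genes differed in 7 of 18 toward H82 and 1 toward H211 (-0.391, 0.00187). Adjusted over the list alone, the counts were 17 and 1 for cholesterol, 14 and 2 for interferon-stimulated and 12 and 1 for ion channel genes, and otherwise the same. The other 18 lists had adjusted p = 0.182 to 0.988.

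**Figure D4:**
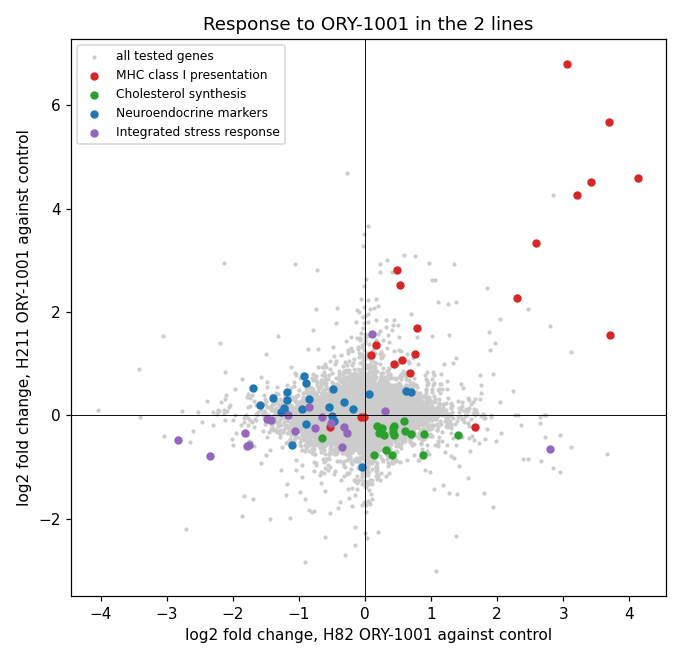
Log2 fold change with ORY-1001 in H82 (horizontal axis) and H211 (vertical axis) for all tested genes, with 4 gene lists in colour; each point is a gene. Cholesterol synthesis genes had a median of 0.427 in H82 and -0.361 in H211, and MHC class I genes 0.759 and 1.56.

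Over all genes, 4956 differed in their response, 2747 toward H211 and 2209 toward H82, with 835 at least 2-fold; totals without the mitochondrial genes gave 2220 and 2545, and the fit without the 4 libraries 3038. Among the largest differences were MPO (-4.42, adjusted p = 0.039), SRGN, a granule proteoglycan of blood cells (-3.73, 0.0388), and SNORD15B (4.6, 0.0204). MPO and SRGN each lost the call without any 1 library of H82 (adjusted p up to 0.084 and 0.0766) and without H211 ORY-1001 replicate 1 or 2 (up to 0.0881 and 0.0894); SRGN also lost it without H211 control replicate 1 or 2 (0.0871 and 0.0731). Single libraries of H211 moved these values. Without control replicate 1, 2 or 3 or ORY-1001 replicate 3, MPO stood at -3.096, -5.136, -5.018 and -5.416. Without control replicate 1 or 3 or ORY-1001 replicate 1 or 3, SRGN stood at -3.062, -4.497, -3.14 and -4.895. SNORD15B was listed at 0 in H211 controls and at 0, 23.62 and 0 with ORY-1001; its difference was 3.055 without ORY-1001 replicate 2 and 5.366 without replicate 1 or 3.

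Genes called in both lines numbered 1483, 1050 of them in the same direction and 433 in opposite directions. Of these, 499 rose in both (264 for independent lists; Fisher's exact test, odds ratio 2.68, p = 3.6e-55) and 551 fell in both (355; odds ratio 2.03, p = 4.2e-33). With totals without the mitochondrial genes, these numbers were 329 and 697. Fewer than for independent lists were higher in H82 and lower in H211 (192 against 283; odds ratio 0.604, Fisher's exact p = 4.5e-11) or the other way (241 against 331; 0.649, Fisher's exact p = 1.3e-09). Genes are not independent, so these p-values overstate the evidence. H82 ORY-1001 replicates 1 and 2 and H211 ORY-1001 replicate 3 were alike in HBG2, at 0, 0.1204 and 0, and no control was near them. Shared directions therefore cannot be told apart from what these treated libraries had in common. Across genes, the fold changes correlated at Pearson's r = 0.134 and Spearman's rho = 0.143, and r = 0.442 among genes called in both. At least 2-fold in both lines, 16 genes rose and 3 fell; without the 4 libraries 183 genes were called in the same direction.

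Averaged over both lines, 6272 genes changed, 2814 higher and 3458 lower (2370 and 3862 with totals without the mitochondrial genes), and 117 at least 2-fold; 3670 were called without the 4 libraries. TAP1 rose by a mean log2 fold change of 4.37, PSMB8 by 4.69 and B2M by 2.29 (adjusted p = 1.95e-12, 2.4e-11 and 2.04e-10). MHC class I genes rose in 18 of 21 and fell in 1 (median 1.25, adjusted p = 4.21e-15), interferon-stimulated genes in 17 of 25 and 2 (0.67, 9.78e-10), and TGF-beta genes in 9 of 20 and 4 (0.221, 0.00531). Integrated stress response genes fell in 16 of 19 and rose in 3 (median -0.501, adjusted p = 5.85e-07). These 4 calls held with an estimated correlation (adjusted p = 0.00973, 0.0238, 0.0494 and 0.00948). Neuroendocrine markers fell in 15 of 25 and rose in 2 (adjusted p = 0.000885), tuft-cell genes in 11 of 18 and 1 (0.00253), and ion channels and synapse genes in 9 of 19 and 1 (0.0403); chemokines and cytokines rose in 4 of 6 and fell in 0 (0.0291). These calls were lost with an estimated correlation (adjusted p = 0.278, 0.377, 0.278 and 0.278). Adjusted over the list alone, the counts were 18 and 3 for interferon-stimulated, 10 and 4 for TGF-beta, 16 and 2 for neuroendocrine and 10 and 1 for ion channel genes, and otherwise the same. The other 17 lists had adjusted p = 0.0512 to 0.817.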

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

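The tests of technical explanations in this part, and the removal of an effect before regrouping, were chosen after the result was seen; the other counts over splits of the samples were planned. The response to ORY-1001 differed between H211 and H82 for 4956 genes by the test of the difference itself, and so did each list and gene given here. The average effect of each gene was removed and the libraries were regrouped within the lines. Of 100 regroupings 1 gave a count as large, the real one (highest other 2). A chance division of these libraries can thus be excluded for the difference. The libraries of a group may come from 1 culture, so chance differences between cultures were not tested. Nor were the splits of the H82 and H211 libraries in blood transcripts. For the 6272 genes changed on average, with the difference removed, 1 of 100 was as large (highest other 2). For the 1050 genes called in the same direction, with no effect removed, 1 of 100 was (highest other 433, with treated and control swapped in H211). Regroupings that mixed treated and control libraries of a line left few calls in it, so their counts were 0 or 1. This comparison therefore does not test whether the lines share directions. A chance division of these libraries can be excluded for the average as well, within the same limits. For single lines and for the controls the 10 splits of 6 libraries are too few for a share under 0.05. The real split was the 1 as large in each case, with 6643 genes in H82 (highest other 5), 2868 in H211 (4) and 12442 between the controls (1).

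Differences below are H211 effects minus H82 effects on the log2 scale, medians for lists. Lists differed by 0.558 (MHC class I), 0.611 (interferon-stimulated), 0.989 (neuroendocrine), -0.391 (tuft-cell), 0.924 (ion channels and synapse), -0.788 (cholesterol synthesis) and 1.006 (integrated stress response). The lists chosen later differed by -1.214 (hypoxia), 1.527 (immediate early) and 0.217 (ribosomal protein). Of these, cholesterol, stress response, hypoxia and immediate early lists kept their call with an estimated correlation (adjusted p = 0.00271, 0.00605, 2.45e-05 and 0.00229).

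Among antigen presentation and interferon genes the differences were 0.454 for TAP1, -2.149 for TAP2, 1.978 for PSMB8, 3.741 for PSMB9 and 1.064 for HLA-C. TAP1 turned to -0.915 with a pseudocount of 0.1, where PSMB8 missed the threshold (0.958, adjusted p = 0.0707). IFITM3 differed by 2.336, ISG15 by 0.998, USP18 by -1.778 and IFI6 by -0.958. Among genes that fell in H82 they were 4.133 for NSG1, 3.384 for PRSS56, 2.841 for CPLX3, 2.116 for PCOLCE, 2.355 for ASNS, 0.724 for SYT1, 1.168 for NCAM1, 1.223 for SYN1 and 0.692 for INSM1. SNORD15B differed by 4.596. Among genes that fell in H211 they were -2.413 for PTGS1, -2.352 for S100A14, -1.75 for ANXA1, -2.45 for SPIB, -2.011 for PRKAR2B, -1.363 for ALDH1A1 and -1.403 for CHAT.

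Cholesterol genes differed by -1.79 (HMGCS1), -1.062 (FDFT1), -1.646 (INSIG1) and -0.503 (SQLE). Stress and hypoxia genes differed by -3.448 (DDIT4), -3.546 (MIR210HG), 1.46 (ATF3), 0.753 (PSAT1), 0.612 (ATF5), -1.214 (LDHA) and -0.76 (NDRG1). Immediate early genes differed by 4.947 (EGR1), 2.075 (IER2) and 3.539 (JUN). Growth and cell cycle genes differed by -0.27 (ID3), -1.141 (ID1), 0.23 (TOP2A), 0.236 (MCM3) and 0.567 (MYC).

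Genes named from the control cultures differed by 0.989 (RTN1), 0.49 (DLL3), -0.736 (BMX), 0.331 (OTX2), 2.216 (KRT19), 0.39 (HIST1H1C), -0.421 (MYCL), -0.371 (SOX4), 0.386 (SOX11), 1.058 (NFIB), 1.763 (YAP1) and 0.901 (GFI1B). The ribosomal genes RPL32 and RPL13 differed by 0.279 and 0.386. OTX2, SOX11, HIST1H1C and RPL32 are close to the threshold. OTX2 lost its call when H211 ORY-1001 replicate 1 or 2 or any library of H82 but ORY-1001 replicate 1 was left out (adjusted p 0.053 to 0.0849). SOX11 lost it without any library but H82 ORY-1001 replicate 2 or 3 and H211 ORY-1001 replicate 3 (0.0509 to 0.0745). HIST1H1C lost it without any but H82 control replicate 1, H82 ORY-1001 replicate 2, H211 control replicate 3 and H211 ORY-1001 replicate 2 (0.0638 to 0.101). RPL32 lost it without H82 control replicate 2 or 3, H82 ORY-1001 replicate 2 or 3, H211 control replicate 1 or 2 or H211 ORY-1001 replicate 1 (0.0549 to 0.0624).

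MPO (-4.417) belongs to the blood-cell transcripts that varied between libraries of the same group. SRGN (-3.728) is not one of the 7 genes tested as a panel. It varied in H211, at 11.88, 4.902 and 0.763 in controls and 0.4897, 0.5098 and 15.98 with ORY-1001, and stood at 14.44, 14.11 and 11.25 in treated H82. For the spread among the H211 controls, which had no ORY-1001, the values argue against a response to it. MPO was at 24.27, 0.4935 and 0.7582 there, LYZ at 0.3561, 22.99 and 0.2259, and HBG2 at 47.39, 40.62 and 18.67. For the treated libraries a response stays open. Of the panel of 7 blood-cell genes, 0 had all treated libraries on the same side of all controls in both lines. In H82 alone LYZ, MPO and TYROBP did, with all 3 treated libraries higher (chance gives 10% for 3 against 3), and in H211 alone 0 did. Reads or RNA from other samples may account for it: 100% of the panel ran over a 5-fold range inside a group, against 1.24% of 5744 other genes of like level (71; one-sided Fisher's exact test, p = 6.4e-14). The panel was chosen for this pattern and its source is in no table, so this explanation stays open, and the most abundant panel gene, HBG2, reached 53.02.

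Genes abundant in a line left traces in the other. Of 2771 genes at 100 or more in a line, 1 lay under 0.1% of that level in the other, which is consistent with a small share of reads passing between libraries of the lines. The lowest share was 1.23% of 1366 genes of H82 in H211 and, above 0, 0.406% of 1405 genes of H211 in H82, with 1st percentiles of 1.56% and 0.856%. Low expression of the genes themselves stays open, since 1 of the 2771 was listed at 0 and no table forbids it.

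Cholesterol synthesis genes rose in H82 and fell in H211. Scaling between libraries is argued against, since over the scaling alternatives the median difference nearest 0 was -0.782 and the largest adjusted p 2.46e-12. Reads shared between the lines are argued against as well, since 0 of the 18 genes lay under 3% of the level in the other line. What makes the lines differ stays open. ORY-1001 and culture conditions were not tested apart, and the medium and density at harvest are not in the labels.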

How the results depend on the processing

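Chosen after the data were examined were the fits without the 4 libraries that stood apart in blood transcripts, without genes under 3% of their level in the other line, and with at least a 2-fold change, and all values of the hypoxia, immediate early and ribosomal lists. Each result was recomputed with 1 choice changed at a time, and each of the 12 libraries was left out in turn. For the average over both lines this covered the count and the genes of interest, and not PSMB8 or the lists. The averaged lists that lost their call with an estimated correlation are given above and are not counted here. Of values set against their reported ones, 142 counts stayed within 1.5 times and 10 did not. For lists, 2583 values kept sign and side of the threshold, 68 lost the call, 68 gained a call and 85 turned sign. For named genes these numbers were 8655, 346, 47 and 88. The depth of the libraries is unknown, so what it limits cannot be stated.

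Apart from the 3 fits chosen later, the alternatives kept the 6 counts of genes within 1.5 times, and leaving out 1 library gave 5819 to 6644 in H82, 1997 to 3031 in H211, 4379 to 4655 for the difference, 5708 to 6132 for the average, 12102 to 12464 in the controls and 704 to 1021 in the same direction. At least 2-fold, the counts were 529, 231, 835, 117, 5852 and 19. Without the 4 libraries they were 665 in H211, 3038 for the difference, 3670 for the average and 183 in the same direction, and within 1.5 times in H82 (5759) and the controls (11335). This fit has fewer samples, and the lone control of H211 is assumed to vary like the other groups. It keeps H82 ORY-1001 replicates 1 and 2, with HBG2 at 0 and 0.1204 against 23.9, 28.15 and 22.43 in the H82 controls. The H82 count there thus does not show that it is free of what set the libraries apart in blood transcripts. Without genes under 3% the counts were 6658, 2903, 4448, 5770, 11274 and 1051; genes left out there have no value, which follows from the construction. Totals without the mitochondrial genes shifted the median of all genes by 0.16 on the log2 scale between the controls, from -0.023 to 0.137, and no other scaling shifted it by over 0.1.

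The replicate number was tried as a block, since libraries with the same number could share a day. Deviations of same-numbered libraries correlated at -0.08 to 0.045 over 6 pairs of a treated and a control library of a line, and at -0.08 to 0.058 over all 18 pairs, so the block is given as an alternative. H82 control replicate 1 and H211 control replicate 3, with different numbers, reached 0.089. H82 ORY-1001 replicate 3 reached 0.085 with H211 control replicate 1, and H82 ORY-1001 replicate 1 reached 0.081 with H211 ORY-1001 replicate 3. These highest values between groups all joined libraries alike in HBG2. Pairs alike in HBG2 also lay under 0. H82 control replicates 2 and 3 had -0.043 and -0.051 with H211 control replicate 3. H82 ORY-1001 replicate 2 had -0.022 with H211 ORY-1001 replicate 3, and H82 ORY-1001 replicate 3 had -0.03 with H211 control replicate 2. No grouping other than the number was tried as a block. The counts with the block were 6219 in H82, 2204 in H211, 4325 for the difference, 5791 for the average and 784 in the same direction. With the block, interferon genes in H82 lost their call (0.184, 0.0503), and neuroendocrine (0.204, 0.0429) and lymphoid and blood genes (-1.948, 0.034) gained a call in H211. The block gives no value for the controls, and each line fitted alone gives none for the difference, the average or the controls.

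In what follows each name carries, in parentheses, the log2 fold change of a gene or the median of a list and then the adjusted p. Genes are named here where they turned sign, and lost and gained calls are named for lists. Named genes also lost and gained calls: 16 and 0 with a pseudocount of 0.1, 11 and 6 with one of 5, 23 and 0 with no filter, 0 and 1 among genes at 5 or more, 8 and 4 with quantile normalization, and 5 and 3 with totals without the mitochondrial genes. These were 7 and 2 with no trend and a robust prior, 2 and 3 with library weights, 13 and 2 with each line alone, 15 and 3 with the block, 41 and 4 without the 4 libraries and 44 and 0 without genes under 3%. The cause was not tested unless stated. With a pseudocount of 0.1, signs turned for immune ligand (0.01, 0.509) in H211 and TAP1 (-0.915, 0.011), IFIH1 (-1.409, 0.00054), Notch (0.207, 0.92), TGF-beta (0.012, 0.807) and chemokine (0.119, 0.965) for the difference. Calls were lost by MHC class I (0.308, 0.114) and interferon (0.657, 0.0802) for the difference and non-neuroendocrine (2.858, 0.0709) in the controls. In H211, calls were gained by neuroendocrine (0.46, 0.021) and epithelial-mesenchymal (0.124, 0.0304). With a pseudocount of 5, signs turned for POU2F3 (-0.027, 0.83) for the difference and NEUROD1 (-0.015, 0.751) for the average. Calls were lost by interferon (0.076, 0.0509) in H82 and chemokine (0.13, 0.0809) in H211. With no filter on low values, signs turned for growth arrest (0.027, 0.934) in H82, immune ligand (0, 0.88) in H211, MHC class II (-0.207, 0.833) and immune ligand (0.031, 0.883) for the difference and subtype factor (0.276, 0.909) in the controls. Calls were gained by TGF-beta (0.077, 0.0267) and cell cycle (-0.067, 0.0309) in H82 and neuroendocrine (0.178, 0.0117), epithelial-mesenchymal (0.044, 0.0238) and lymphoid and blood (-0.272, 0.001) in H211. Calls were gained by neuronal bHLH (0.183, 0.00942), myeloid (-0.791, 0.00942), epithelial-mesenchymal (0.261, 0.0293) and fibroblast (0.183, 0.0461) for the difference and MHC class I (1.001, 0.0302) in the controls. Among genes at 5 or more in 3 libraries, signs turned for Notch (0.027, 0.546), epithelial-mesenchymal (-0.082, 0.515), growth arrest (-0.022, 0.515) and immune ligand (0.048, 0.713) in H211 and nucleic acid sensing (-0.023, 0.651), Notch (0.052, 0.83), epithelial-mesenchymal (-0.038, 0.631) and immune ligand (0.217, 0.83) for the difference. In the controls, signs turned for Notch (-0.092, 0.938) and hypoxia (-0.018, 0.96). Calls were lost by ion channel (-0.537, 0.0509) in H82 and non-neuroendocrine (1.994, 0.115) and ion channel (-2.239, 0.233) in the controls. Genes and lists with too few values at 5 or more have no value there.

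With median-of-ratios scaling, signs turned for AURKB (0.005, 0.98) in H211 and immune ligand (0.022, 0.854) in the controls. Calls were lost by chemokine (0.358, 0.0508) in H211 and non-neuroendocrine (1.607, 0.0533) in the controls. With quantile normalization, signs turned for KDM1A (-0.043, 0.48), CDC20 (-0.01, 0.901), KCNH2 (0.032, 0.778), MYCL (0.002, 0.994), RPL32 (-0.034, 0.485) and nucleic acid sensing (-0.007, 0.508) in H82. Signs turned for KDM1A (-0.032, 0.69), DLL3 (0.003, 0.981), ASCL2 (-0.034, 0.816), LDHA (-0.084, 0.179) and Notch (0.003, 0.378) in H211 and KDM1A (0.011, 0.911), B2M (0.028, 0.839) and growth arrest (0.044, 0.851) for the difference. Signs turned for KDM1A (-0.037, 0.374) and NEUROD1 (-0.002, 0.979) for the average and KDM1A (-0.076, 0.133) in the controls. Calls were lost by chemokine (0.34, 0.0595) and ribosomal (0.046, 0.129) in H211, ribosomal (0.085, 0.131) for the difference and non-neuroendocrine (1.529, 0.0586) and ribosomal (-0.339, 0.588) in the controls. In H82, calls were gained by TGF-beta (0.091, 0.0483) and cell cycle (-0.117, 0.0452). With totals without the mitochondrial genes, signs turned for KDM1A (-0.034, 0.706), ASCL2 (-0.026, 0.863), LDHA (-0.028, 0.675), nucleic acid sensing (-0.037, 0.615) and growth arrest (-0.042, 0.942) in H211, cell cycle (-0.021, 0.81) for the difference and NEUROD1 (-0.003, 0.976) for the average. In the controls, signs turned for LSD1-CoREST (0.152, 0.971) and immune ligand (0.124, 0.768). In the controls, calls were lost by interferon (1.05, 0.0619), nucleic acid sensing (0.999, 0.0506), non-neuroendocrine (1.781, 0.116), cell cycle (-0.219, 0.116) and stress response (-0.451, 0.0585). In H211, calls were gained by neuroendocrine (0.207, 0.0154) and epithelial-mesenchymal (0.054, 0.0213). With library weights, signs turned for RPL32 (-0.021, 0.79) in H82, AURKB (0.016, 0.877) and nucleic acid sensing (-0.014, 0.783) in H211, B2M (0.005, 0.975) and growth arrest (0.002, 0.934) for the difference and KDM1A (-0.005, 0.902) in the controls. In H211, the call was lost by chemokine (0.324, 0.0551). In H211, a call was gained by neuroendocrine (0.259, 0.0176). With each line fitted alone, a call was gained by lymphoid and blood (-1.948, 0.0415) in H211. The cause was not tested.

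Without the 4 libraries, signs turned for YAP1 (-0.003, 0.99), REST (-0.028, 0.916), SPIB (-0.031, 0.883), MYCN (-0.153, 0.848), nucleic acid sensing (-0.002, 0.747) and ribosomal (0.022, 0.947) in H82. In H211, signs turned for KDM1A (-0.011, 0.955), INSM1 (-0.136, 0.62), CPLX3 (-0.041, 0.89), EPCAM (0.027, 0.956), MYCN (-0.177, 0.925), SOX4 (0.094, 0.71) and neuroendocrine (-0.042, 0.956). In H211, signs turned for Notch (0.019, 0.297), neuronal bHLH (-0.019, 0.889), LSD1-CoREST (0.004, 0.889), myeloid (0, 0.711), growth arrest (-0.039, 0.889), immune ligand (0.017, 0.711) and mitochondrial (0.227, 0.317). For the difference, signs turned for HIST1H2AC (-0.083, 0.85), AURKB (-0.1, 0.394), MYCN (-0.024, 0.986), Notch (0.185, 0.752), TGF-beta (0.009, 0.819), cell cycle (-0.008, 0.752) and lymphoid and blood (2.659, 0.00886). In the controls, signs turned for HLA-B (-0.307, 0.148), myeloid (0, 0.925), lymphoid and blood (-0.068, 0.921) and hypoxia (-0.012, 0.729). Calls were lost by interferon (0.099, 0.0671) in H82, chemokine (0.225, 0.19) and histone (0.261, 0.112) in H211 and ribosomal (0.055, 0.165) for the difference. In the controls, calls were lost by interferon (0.842, 0.0567), nucleic acid sensing (0.621, 0.0648), non-neuroendocrine (1.369, 0.0989), cell cycle (-0.468, 0.0633) and stress response (-0.629, 0.0564). Calls were gained by myeloid (0.964, 0.00143), chemokine (0.499, 0.0497) and lymphoid and blood (-2.687, 0.00143) in H82 and myeloid (-0.993, 0.00128) for the difference. Fewer samples are the construction of this setting, and no other cause was tested.

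With an estimated correlation, calls were lost by interferon (0.184, 0.432), neuroendocrine (-0.892, 0.143) and ion channel (-0.587, 0.143) in H82 and tuft-cell (-0.474, 0.189), cell cycle (-0.053, 0.301), chemokine (0.353, 0.301), histone (0.319, 0.074) and ribosomal (0.14, 0.259) in H211. For the difference, calls were lost by MHC class I (0.558, 0.163), interferon (0.611, 0.163), neuroendocrine (0.989, 0.163), tuft-cell (-0.391, 0.431), ion channel (0.924, 0.163) and ribosomal (0.217, 0.368). In the controls, calls were lost by interferon (0.889, 0.264), nucleic acid sensing (0.822, 0.169), neuroendocrine (-1.587, 0.226), non-neuroendocrine (1.606, 0.264), tuft-cell (4.675, 0.226), neuronal bHLH (-1.587, 0.169) and epithelial-mesenchymal (2.652, 0.187). In the controls, calls were lost by cell cycle (-0.392, 0.264), ion channel (-1.451, 0.264), cholesterol (0.605, 0.169), stress response (-0.625, 0.169), histone (1.052, 0.169) and ribosomal (-0.526, 0.796). The medians are the same, and the test allows for correlation among list members. With fry, calls were gained by nucleic acid sensing (0.003, 0.00417), Notch (0.052, 0.000489), subtype factor (-0.099, 0.0098), neuronal bHLH (-0.109, 0.00101) and LSD1-CoREST (-0.067, 0.0098) in H82. In H82, calls were gained by TGF-beta (0.096, 4.82e-08), cell cycle (-0.067, 0.000495), immune ligand (-0.093, 0.00109), chemokine (0.526, 0.0098) and fibroblast (0.042, 0.0098). In H211, calls were gained by nucleic acid sensing (0.024, 0.0275), Notch (-0.014, 0.00154), subtype factor (0.084, 0.013), epithelial-mesenchymal (0.111, 3.08e-05), immune ligand (-0.01, 0.013), fibroblast (0.109, 0.00226) and lymphoid and blood (-1.948, 0.0301). For the difference, calls were gained by subtype factor (0.175, 0.00169), neuronal bHLH (0.31, 0.00108), TGF-beta (-0.125, 0.0498), epithelial-mesenchymal (0.274, 0.000209) and fibroblast (0.298, 0.00112). In the controls, calls were gained by MHC class I (1.017, 2.05e-07), MHC class II (0.312, 4.97e-06), subtype factor (-0.265, 3.06e-07), LSD1-CoREST (-0.031, 0.00338), TGF-beta (0.335, 2.11e-10) and growth arrest (0.721, 2.9e-10). In the controls, calls were gained by immune ligand (-0.002, 0.00781), fibroblast (0.646, 1.72e-07), lymphoid and blood (0.769, 0.00096), hypoxia (0.014, 0.000916) and immediate early (0.174, 0.0058). Fry tests whether a list's genes move, on balance, to 1 side, and does not compare the list with other genes.

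With 1 library left out, lists that turned sign or changed sides of the threshold, and named genes that turned sign, had these lowest and highest values; the cause was not tested. In H82 these were YAP1 (-0.003 to 0.068), REST (-0.051 to 0.152), GFI1B (-0.27 to 0.079), SPIB (-0.031 to 0.371), EPCAM (-0.024 to 0.154), KCNH2 (-0.113 to 0.027), MYCN (-0.358 to 0.476) and MYCL (-0.065 to 0.017). Others in H82 were RPL32 (-0.053 to 0.051), interferon (0.099 to 0.209), nucleic acid sensing (-0.028 to 0.048), non-neuroendocrine (-0.018 to 0.08), TGF-beta (0.047 to 0.134), immediate early (-0.105 to 0.068) and ribosomal (-0.115 to 0.022). In H211 these were MPO (-1.755 to 0.565), NSG1 (-0.005 to 0.258), PRSS56 (-0.066 to 0.029), SNORD15B (0 to 2.311), CPLX3 (-0.012 to 0.231), SRGN (-1.771 to 0.062), SYN1 (-0.052 to 0.144), DLL3 (-0.053 to 0.015) and OTX2 (-0.02 to 0.141). Others in H211 were EPCAM (-0.033 to 0.008), AURKB (-0.047 to 0.072), SOX4 (-0.077 to 0.012), MHC class II (-0.181 to 0.195), nucleic acid sensing (-0.071 to 0.103), neuroendocrine (0.112 to 0.331), Notch (-0.053 to 0.015), neuronal bHLH (-0.008 to 0.134) and myeloid (-0.794 to 0.092). Others in H211 were epithelial-mesenchymal (0.092 to 0.221), cell cycle (-0.095 to -0.053), growth arrest (-0.006 to 0.037), immune ligand (-0.025 to 0.077), chemokine (0.208 to 0.377), lymphoid and blood (-2.632 to -0.856) and mitochondrial (-0.327 to 0.05). For the difference these were KDM1A (-0.054 to 0.001), B2M (-0.083 to 0.03), EPCAM (-0.167 to 0.012), HIST3H2A (-0.164 to 0.001) and MYCN (-0.304 to 0.53). Others for the difference were MHC class II (-0.027 to 0.363), Notch (-0.037 to 0.061), growth arrest (-0.139 to 0.023), chemokine (-0.153 to 0.033) and lymphoid and blood (-0.895 to 0.684). For the average these were NEUROD1 (-0.019 to 0.073). In the controls these were KDM1A (-0.009 to 0.012), non-neuroendocrine (1.518 to 1.725), immune ligand (-0.054 to 0.023) and hypoxia (-0.008 to 0.07).

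Named genes that changed sides of the threshold with 1 library left out follow, with the libraries by number of the replicate and the lowest and highest adjusted p of those fits; the cause was not tested. In H82, calls were lost by SNORD15B without H82 control 1 or 3 (0.0527 to 0.0532), PTGS1 without any H82 control or H82 ORY-1001 1 or 2 (0.053 to 0.0963) and HIST3H2A without H82 control 1 or 2 or H82 ORY-1001 1 (0.0645 to 0.0938). Also lost in H82 were those of POU2F3 without any but H82 control 2 and H82 ORY-1001 1 (0.0541 to 0.164), OTX2 without H82 control 1 or 2 or H82 ORY-1001 2 or 3 (0.0573 to 0.0659) and PROX1 without H82 control 2 or 3 or H82 ORY-1001 1 or 3 (0.0534 to 0.106). Also lost in H82 was that of MPO without H82 ORY-1001 3 (0.052). In H82, calls were gained by HES1 without H82 control 1 (0.0469), EGR1 without H82 control 1 (0.0262) and NFKBIA without H82 control 1 (0.0141). Also gained in H82 were those of BMX without H82 control 2 or H82 ORY-1001 1 (0.0233 to 0.0396), HIST1H2AC without H82 control 3 (0.0411) and GFI1B without H82 ORY-1001 3 (0.0409). In H211, calls were lost by HIST2H2BE without any but H211 control 1 (0.0532 to 0.156), HIST1H2AC without H82 control 2, H82 ORY-1001 2, H211 control 1 or 2 or any H211 ORY-1001 (0.0611 to 0.142) and SYT1 without H82 control 2 or 3, H211 control 1 or 2 or any H211 ORY-1001 (0.0523 to 0.119). Also lost in H211 were those of S100A16 without H211 control 1 or H211 ORY-1001 2 or 3 (0.0501 to 0.0606) and PCOLCE without H211 control 2 or 3 or H211 ORY-1001 2 (0.066 to 0.0954). In H211, calls were gained by KCNH2 without H82 ORY-1001 3 (0.0353), NOTCH2 without H211 control 1 (0.0498) and NEUROD1 without H211 control 2 (0.0474). Also gained in H211 was that of CDC20 without H211 ORY-1001 1 (0.0462). For the difference, calls were lost by MPO without any but the H211 controls and H211 ORY-1001 3 (0.0536 to 0.0881), SRGN without any but H211 control 3 and H211 ORY-1001 3 (0.0583 to 0.0894) and OTX2 without any H82 control, H82 ORY-1001 2 or 3 or H211 ORY-1001 1 or 2 (0.053 to 0.0849). Also lost for the difference were those of SOX11 without any but H82 ORY-1001 2 and 3 and H211 ORY-1001 3 (0.0509 to 0.0745), HIST1H1C without any but H82 control 1, H82 ORY-1001 2, H211 control 3 and H211 ORY-1001 2 (0.0638 to 0.101) and RPL32 without H82 control 2 or 3, H82 ORY-1001 2 or 3, H211 control 1 or 2 or H211 ORY-1001 1 (0.0549 to 0.0624). For the difference, calls were gained by NFKBIA without H82 control 3 (0.0398), NEUROD1 without H211 control 2 (0.0248) and HLA-B without H211 control 2 (0.000743). Also gained for the difference was that of S100A16 without H211 ORY-1001 2 (0.0415). For the average, a call was lost by POU2F3 without any but H82 control 2, H82 ORY-1001 1 and H211 ORY-1001 2 (0.0537 to 0.0761). For the average, a call was gained by NOTCH2 without H82 ORY-1001 1 or H211 control 1 (0.0442 to 0.0477). Between the controls, calls were gained by HES1 without H82 control 1 (0.0491) and HLA-B without H211 control 3 (0.00808).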

Other observations

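The hypoxia, immediate early and ribosomal protein lists and every test of them were chosen after their genes were seen in the data. In treated H82, 22 of 27 hypoxia genes rose and 1 fell, and 23 and 1 adjusted over the list alone (median log2 fold change 0.906, adjusted p = 1.57e-15, and 6.46e-05 with an estimated correlation). DDIT4, which is also on the stress response list, rose 7.16-fold to 210 ± 8.7 (SD, n = 3), and LDHA, lactate dehydrogenase, 2.38-fold, from 740 ± 14.1 to 1758 ± 33. MIR210HG was 17.8-fold higher, from 0.471 to 8.37. In H211 the list went the other way, with 1 higher and 12 lower, and 2 and 15 adjusted over the list alone (median -0.211, adjusted p = 1.71e-05, and 0.00211 with an estimated correlation), and NDRG1, a stress-regulated gene, was 1.86-fold lower. The difference between the lines was called in 24 genes, all toward H82 (median -1.214, adjusted p = 7.5e-20). As a hypothesis, lower oxygen in the treated H82 cultures may account for this. The list was chosen from these values, so the 22 genes do not test it, no oxygen or density is recorded, and ORY-1001 itself cannot be told apart from it.

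In treated H211, 13 of 17 measured immediate early genes rose and 0 fell, with the same counts adjusted over the list alone (median log2 fold change 1.85, adjusted p = 5.81e-19, and 0.000519 with an estimated correlation). JUN, a subunit of AP-1, rose 7.56-fold, from 11.9 ± 0.671 to 89.6 ± 1.09 (SD, n = 3), and IER2 4.91-fold, from 20.4 ± 0.656 to 100 ± 2.5. In H82 the list had 5 higher and 3 lower (median -0.024, mean -0.016, adjusted p = 0.714), its median and test differing in sign. The difference between the lines was called in 13 genes toward H211 and 1 toward H82 (median 1.527, adjusted p = 1.63e-10). As a hypothesis, handling or medium at harvest may account for it. The list was chosen from these values, so the 13 genes do not test it, and harvest times are not in the labels, so a response to ORY-1001 cannot be told apart from it.

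Ribosomal protein genes counted 0 higher and 6 lower of 18 in H82, the same adjusted over the list alone (median -0.035, adjusted p = 0.5). In H211 they counted 3 higher and 0 lower, and 8 and 0 adjusted over the list alone (median 0.14, adjusted p = 0.000175). That call was lost with an estimated correlation (adjusted p = 0.259) and with quantile normalization (median 0.046, adjusted p = 0.129). RPL32 rose 1.22-fold and RPL13 1.15-fold in H211; RPL13 lost its call with quantile normalization (adjusted p = 0.607).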
